A study of Caenorhabditis elegans with 4 samples.

How the data were processed

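Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to map where NHR-6 sits on the genome of Caenorhabditis elegans. NHR-6 is the worm's receptor of the NR4A family of nuclear hormone receptors. Per the labels, the worms were L4 hermaphrodites of strain OP90, grown at 20 °C, which carry a transgene encoding NHR-6 fused to GFP together with a rescuing copy of unc-119, and the fusion protein was pulled down with antibodies against GFP. The series holds 4 samples, namely 2 ChIP libraries and 2 input libraries of total genomic DNA. The labels number the replicates but do not say whether they came from separate cultures, so the spread between them may be technical.

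The data used here were 3 peak lists: 1 for each ChIP replicate and 1 combined list for the whole series. Values of the input libraries were not analysed here. Peaks were called with SPP followed by the irreproducible discovery rate procedure, on genome build WS220, per the file headers and the source field of each line. The aligner, the settings of the caller, the threshold and the way the replicates were combined are not given in the sources used here. Each peak carries a score as the authors deposited it, whose scale is not stated, and a peak number. The score was used only to rank peaks within a list, with ties ordered by peak number. The combined list has 1976 of its 2707 peaks tied at the highest score, so most of its ranking rests on peak number. Its stricter 50% therefore holds only peaks of the highest score and was set by peak number. In the replicate lists 986 and 1966 peaks tie at the highest score. A peak list holds no read counts, so the depth of each library is unknown, and the confidence intervals given here cover the counting of peaks only.

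Coordinates are those of the lists, counted from 1 on WS220. The gene table at hand belongs to build WBcel235. As the builds differ, none of its coordinates were used, and peaks were not assigned to genes. For this reason the tests at promoters, of the 24 gene lists, of the NBRE motif and of the loci carried by the transgene, all laid down before the data were examined, were not run. The rule for named items, the 25 highest-ranked combined peaks, was kept, with regions in place of genes. The span of each chromosome was taken as its largest peak end over the 3 lists.

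Overlap between replicates meant at least 1 bp in common and was compared with 1000 circular shifts of the other list along each chromosome, in a one-sided permutation test whose smallest possible p is 0.001. For ranges of ranks and for the combined list, 100 shifts gave the mean by chance. Scores were compared by Spearman's rho over peaks that overlapped one to one, across peaks, which are not independent replicates, so no p is given. Peaks per chromosome were compared with 10000 multinomial draws in proportion to span (two-sided permutation test, smallest p 0.0001). The name is kept below, although the draws come from a model and nothing is permuted. Benjamini-Hochberg adjustment was over the 6 nuclear chromosomes. The share of peaks in the central 33.3% of each chromosome was compared with binomial draws in the same way. There the adjustment was over the 6 chromosomes and all of them together. The comparison of centres with arms was fixed beforehand, but its boundary was not: the central 33.3% was chosen after the data were seen, and the central 50% was run as an alternative. The draws, like the Fisher's exact tests below, treat peaks as independent, which neighbouring peaks are not, so these p-values are too small. Counting peaks within 10 kb of each other once was added as an alternative for this reason. Confidence intervals are 95% Wilson intervals.

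The search for the fullest window of peaks used 100 kb bins, shuffled whole over the nuclear genome 1000 times. It was designed after a dense stretch on chromosome V had been noticed, and its width of 3.5 Mb was chosen to suit that stretch, so its p-values describe the data from which the window was found. Widths of 2 and 5 Mb were also run.

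The functions were tested on simulated data. Of 100 pairs of independent lists of 2000 peaks, 3 were called at 0.05. Where 50% of peaks were planted as shared, in a subset of pairs, 51.0% were found. These lists were evenly scattered, with 1.97% overlap by shifts, against 24.7% and 21.5% for the longer replicate lists. Of 1000 even lists the size of the combined list, 43 had a chromosome called, but they were drawn from the model that the test itself uses. The window search called 4 of 100 even genomes and found 99 of 100 windows planted at doubled density, with bins independent of each other. The simulations therefore check the code, and not its error rates on clustered peaks. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1.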

Results

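NHR-6::GFP binding in L4 hermaphrodites was recorded in 2 ChIP replicates and in 1 combined list. The combined list held 2707 peaks, of which 2705 were distinct intervals. Together they covered 1.22 Mb, or 1.22% of the nuclear span. The usual peak was 510 bp wide, and 2206 peaks had this width. The replicate lists were much longer. Replicate 1 held 25987 peaks and replicate 2 held 29512, covering 12.4 Mb each. Their usual widths were 530 bp and 456 bp. In replicate 1, 10512 peaks (40.5%) overlapped another peak of the same list, and in replicate 2, 9818 (33.3%) did. In the combined list the share was 4.77%. Counts of replicate peaks are therefore not counts of separate sites. The depth of the libraries is unknown.

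The highest-ranked combined peak lay on chromosome II at 10563365 to 10563677 (build WS220). It was the best-ranked nuclear peak of replicate 2, at rank 10, and stood at rank 13 in replicate 1, where mitochondrial peaks took the first 9 ranks of both lists. Rank 2 lay on chromosome III at 3867390 to 3867717, and was the best-ranked nuclear peak of replicate 1, also at rank 10. Rank 3 lay on III at 10758981 to 10759343, rank 4 on X at 5841109 to 5841462 and rank 5 on V at 14347247 to 14347546. Ranks 6 to 8 were at II 3786590 to 3786880, IV 654762 to 655083 and III 13643481 to 13643800. Of the 25 highest-ranked regions, 9 were on V, 8 on III, 3 on X, 2 on II, 2 on IV and 1 on I. Each was also a peak of both replicates, at rank 205 or better in replicate 1 and at rank 158 or better in replicate 2. All 25 share the highest score, so their order follows the authors' peak number. The genes at these regions were not assigned. The transgene adds copies of the loci it carries, which can add DNA to the immunoprecipitate. Whether any of these regions lies at such a locus was not tested.

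Most of the highest-ranked peaks were listed with less than the usual width. Of the 100 highest-ranked combined peaks, 97 were narrower than the usual width, with a median of 275 bp, against 15.4% of the remaining 2607. Among the 100 highest-ranked nuclear peaks of replicates 1 and 2, 61 and 72 were narrower, against 0.0851% and 0.140% of the rest. Over each replicate list, 99.6% and 99.5% of peaks had exactly the usual width. Whether narrowness reflects binding or the way peaks were called was not tested. A different shape was seen on chromosome III at 7814228 to 7816969, a region of 2742 bp that was the widest of the combined list. It was listed 3 times there, with rank 21 as its best. Replicate 1 listed nearly the same interval 6 times and replicate 2 listed it 3 times.

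The highest-ranked peaks were shared by both replicates, and sharing fell with rank. The first 986 peaks of replicate 1 and the first 1966 of replicate 2 tie at the highest score of their list, so their order follows peak number. Of the 500 highest-ranked peaks of replicate 1, 498 were overlapped by a peak of replicate 2 (99.6%, 95% CI 98.6 to 99.9). The reverse share was 494 of 500 (98.8%, 97.4 to 99.4). At ranks 5001 to 10000 these shares were 61.7% and 56.9%, and beyond rank 20000 they were 37.6% and 30.8%. Circularly shifted lists gave about 24.6% and 21.4% at those lower ranks. Over all peaks, 14264 of 25987 peaks of replicate 1 were overlapped (54.9%), against 24.7% ± 0.348 (SD) by shifts. In replicate 2 the count was 14081 of 29512 (47.7%), against 21.5% ± 0.305 (SD). Both excesses had p = 0.001 in the permutation test, the smallest it can give. With centres required to lie within 100 bp, the shares were 26.4% and 23.2%, against 6.02% and 5.29% by shifts. Among the 1000 highest-ranked peaks of each list, 56.3% of those of replicate 1 were overlapped by one of replicate 2, against 2.65% by shifts, where the choice of 1000 peaks of replicate 2 rests on peak number alone. Over 6428 peaks that overlapped one to one, the scores of the replicates had a Spearman's rho of 0.54 across peaks.

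**Figure D1:**
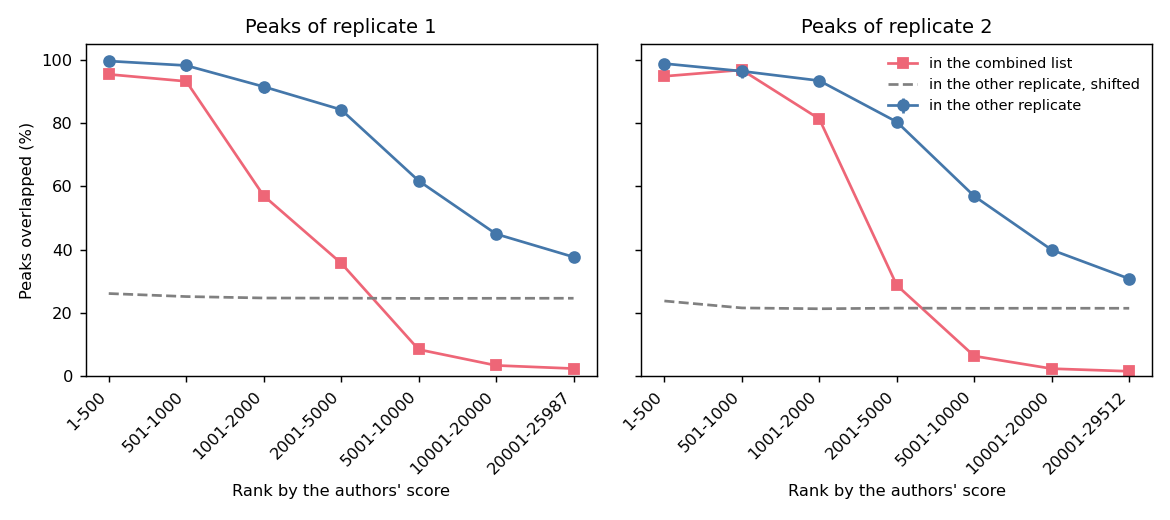
Percent of each replicate's peaks (y axis) that were overlapped by at least 1 bp, by rank of the authors' score (x axis). Blue points are the share overlapped by the other replicate with 95% Wilson intervals, red squares the share overlapped by the combined list, and the dashed line the mean share with the other replicate's list shifted; the share in the other replicate falls from 99.6% to 37.6% in replicate 1 and from 98.8% to 30.8% in replicate 2.

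The combined list drew on both replicates. Replicate 1 overlapped 2680 of the 2707 combined peaks (99.0%, 95% CI 98.6 to 99.3) and replicate 2 overlapped 2702 (99.8%, 99.6 to 99.9), against 21.4% and 23.2% by shifts. Both replicates overlapped 2675 of them, and none was missing from both. The median combined peak had rank 1710 in replicate 1 and 1385 in replicate 2. A total of 1456 combined peaks (53.8%) overlapped one of the 2707 highest-ranked peaks in each replicate.

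Combined peaks were denser on chromosome III and sparser on IV and V than span alone would give. Chromosome III held 460 combined peaks, 1.24 times the number by span (33.4 peaks per Mb). Chromosome IV held 386, a ratio of 0.817 (22.1 per Mb), and V held 478, a ratio of 0.846 (22.9 per Mb). For each of these the adjusted p was 0.0002 in the permutation test. In the same permutation test, chromosomes I, with 443 peaks and a ratio of 1.09, and II, with 449 and a ratio of 1.09, did not pass (adjusted p = 0.068 for both), nor did X with 491 and a ratio of 1.03 (adjusted p = 0.54). The full replicate lists, which hold many more peaks, passed the permutation test on these chromosomes, with small excesses. For replicates 1 and 2 in turn these were 1.08 and 1.08 on I (adjusted p = 0.00015 in each permutation test), 1.04 and 1.03 on II (permutation test, adjusted p = 0.014 and 0.034) and 1.03 and 1.05 on X (permutation test, adjusted p = 0.02 and 0.00036). In that permutation test the call on V was lost in the first 50% of the ranking, which ties in score leave to peak number (ratio 0.885, adjusted p = 0.068), and that on IV when peaks within 10 kb were counted once (ratio 0.908, adjusted p = 0.13).

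The central 33.3% of each chromosome held 1099 of 2707 combined peaks (40.6%, 95% CI 38.8 to 42.5), where even spacing gives 33.3% (permutation test, adjusted p = 0.00023). The share was 50.8% on V, 43.6% on I, 41.2% on II and 39.4% on IV, each past the threshold. In the first 50% of the ranking, again set by peak number, the permutation test no longer called II (38.9%, adjusted p = 0.16) or IV (38.5%, adjusted p = 0.21). The permutation test did not call X, with 31.4% (adjusted p = 0.37), or III, with 37.4% (adjusted p = 0.081). Chromosome III did pass the permutation test without replicate 1 (38.6%, adjusted p = 0.026) and with the central 50% in place of the central 33.3% (57.0%, adjusted p = 0.0036). Over all chromosomes the central 50% held 59.8% of peaks. The share on X was lower than that on the autosomes together, 154 of 491 against 945 of 2216 (42.6%; Fisher's exact test, two-sided, p = 3.6e-06). This test was added after the shares were seen. It sets a single chromosome against a pool and counts peaks as replicates, so its p does not measure the spread between chromosomes. The autosomes themselves ranged from 37.4% on III to 50.8% on V. The 95% intervals of X (27.4 to 35.6) and III (33.1 to 41.9) overlap.

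Along the chromosomes, the median of 197 full bins of 500 kb was 13 combined peaks (quartiles 9 and 17). The fullest bin, with 35, lay on V at 14 to 14.5 Mb, and the only empty one on V at 17 to 17.5 Mb, where the replicates listed 34 and 46 peaks.

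**Figure D2:**
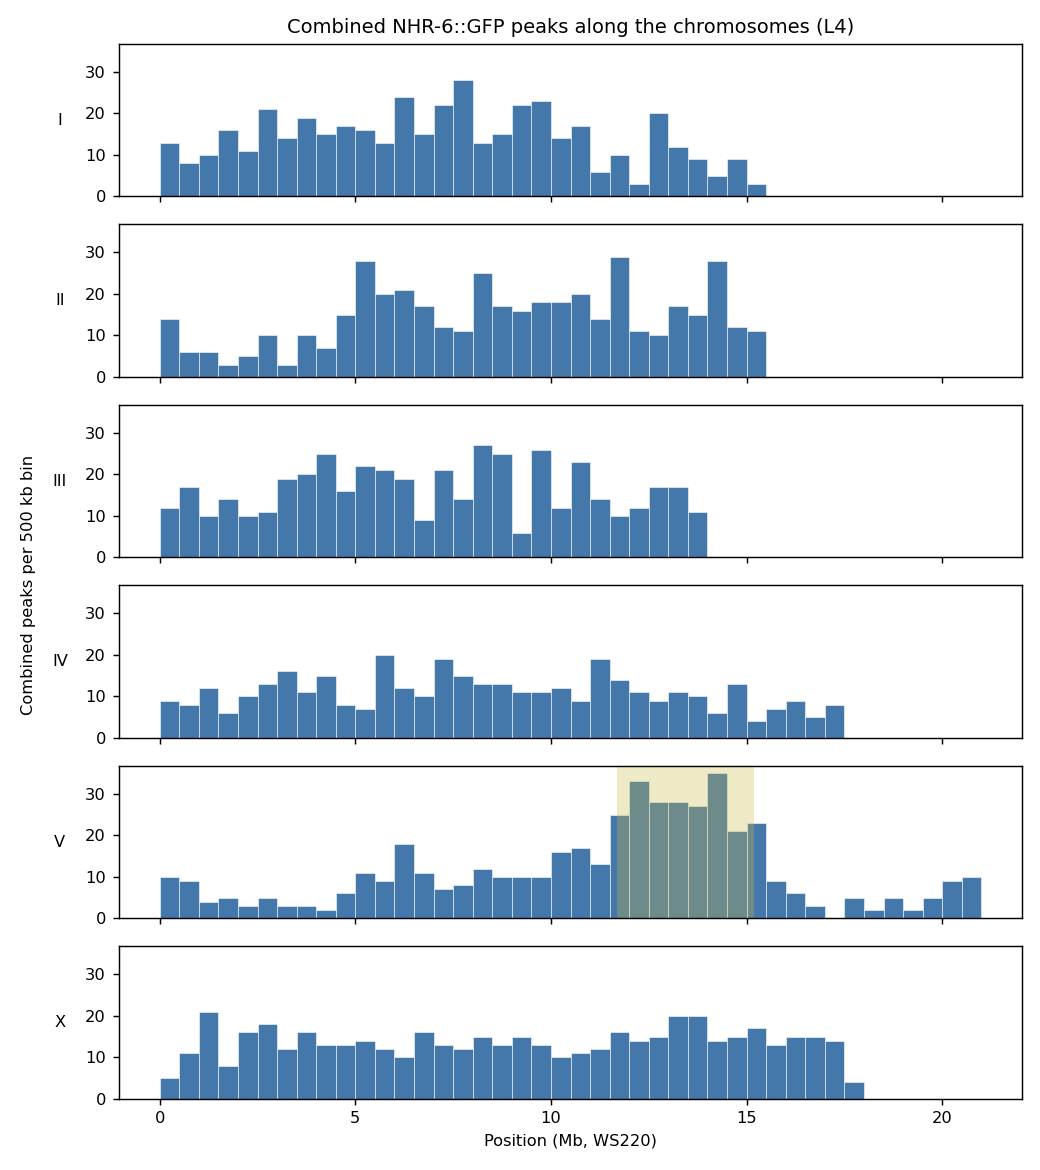
Number of combined peaks (y axis) in each 500 kb bin along the 6 nuclear chromosomes (x axis, Mb on WS220); the last bin of each chromosome is incomplete. The shaded stretch of V, 11.7 to 15.2 Mb, holds 204 peaks, and bins there reach 35 against a median of 13 over full bins.

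Peaks also stood close together more often than under random placement. Counting peaks within 10 kb once left 1748 regions, of which 212 held 3 or more peaks. In 100 random placements along the same chromosomes the mean was 2036 regions, with 126 holding 3 or more and at most 152. Such placement does not keep the broad differences in density along the chromosomes, which by themselves bring peaks together. Local crowding was not separated from them. The largest group, 11 peaks in 36.1 kb on II at 10527571 to 10563677, includes the highest-ranked peak, and the replicates listed 34 and 39 peaks there. Next came 9 peaks in 21.4 kb on V at 14347247 to 14368691, which include rank 5. A group of 8 peaks on V at 11979908 to 12004819 includes rank 16, and one of 8 peaks on II at 5321899 to 5346755 has rank 61 as its best. These groups were picked by size after the data were seen. The largest group in the random placements held 9 peaks, so only the group of 11 exceeded it.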

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

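The tests in this part were chosen after the results were seen. Mitochondrial DNA, which is outside the comparisons of the combined list and enters only the overlap between replicates, carried 22 peaks in replicate 1 and 26 in replicate 2. Without repeated listings these are 11 and 22 distinct intervals. They took the first 9 ranks of both lists, while the combined list held 0. Nuclear peaks of like rank were nearly all kept: of those within the first 250 ranks the combined list held 230 of 233 in replicate 1 (98.7%) and 230 of 231 in replicate 2 (99.6%).

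High rank of mitochondrial peaks was common to both replicates: 17 of 22 in replicate 1 and 19 of 26 in replicate 2 lay within the first 250 ranks. Poor reproducibility of their positions stays open. Of these peaks 22 of 22 in replicate 1 and 25 of 26 in replicate 2 (96.2%) were overlapped by the other replicate, but lists shifted along the molecule gave 96.9% and 93.4% (permutation test, p = 0.45 and 0.67), so its dense coverage nearly fixes that outcome. Signal over the whole molecule from its many copies per cell is another possible explanation. Peaks lay over 12066 bp of its span of 13412 bp (90.0%) in replicate 1, against 63.8% for the fullest nuclear window of that length. In replicate 2 they lay over 64.7% of it, against 62.7%, a margin of only 2.04 percentage points. Those windows are nuclear extremes. Over the whole nuclear span, peaks covered 12.35% in replicate 1 and 12.39% in replicate 2. The reading depends on the criterion: a fixed bound of 50% of the span, tried first, was exceeded in both replicates, and was replaced because nuclear windows exceed it too. Without input values, which were not analysed here, these explanations cannot be told apart, and whether mitochondrial peaks were filtered before the combined list was made is not given in the sources used here. No biological explanation was tested.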

How the results depend on the processing

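Of 92 values under another setting, 77 kept their side of the threshold or stayed within error. Another 7 moved, 4 lost their call, 4 gained one and no called value reversed. The uncalled ratio on X turned from 1.03 to 0.981 without replicate 2. Counting peaks within 10 kb once, leaving out the chromosome V segment, the central 50% of chromosomes, peak numbers in place of scores, nuclear peaks only, and each setting of the segment itself were chosen after seeing the data. The stricter 50% of each ranking, set by peak number in the combined list, held 1353 combined, 12993 replicate 1 and 14756 replicate 2 peaks by construction. It was overlapped by replicate 1 for 99.7% and by replicate 2 for 99.9%. Requiring overlap of 50% of both peaks lowered these shares of the whole combined list to 84.3% and 88.1%. The deficit on V was no longer past the threshold in the stricter 50% (0.885), nor that on IV with peaks within 10 kb counted once (0.908). The central share was no longer past it on II (38.9%) and IV (38.5%) in the stricter 50%, while III passed with the central 50% (57.0%); for these and the lowered shares the cause was not tested. Without the V segment, which lowers the number that span gives to the other chromosomes, I (1.14) and II (1.14) passed as well. Using the 2707 highest-ranked peaks of either replicate alone, of which 2682 (replicate 2) and 2688 (replicate 1) were nuclear, changed no call on peaks per chromosome, though the full replicate lists also called I, II and X. For the central 33.3% it changed that on III, which had 38.6% without replicate 1, a call, and 35.4% without replicate 2. The excess overlap between replicates kept p = 0.001 in the permutation test under each definition run, nuclear peaks only included, though the share itself ranged from 23.2% with centres within 100 bp to 56.4% among the 1000 highest-ranked peaks. No paired analysis was possible because values of the input libraries were not analysed here and no result compares the groups. The alternatives for promoters, gene lists and the NBRE motif were not run, as the builds differ. Depth is unknown, so whether it accounts for replicate 2 having more peaks was not examined.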

Other observations

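All tests in this part were chosen after the pattern was seen. Chromosome V, sparse as a whole, held a dense stretch at 11.7 to 15.2 Mb. It made up 3.49% of the nuclear span and held 204 of 2707 combined peaks (7.54%), which is 58.3 per Mb against 25.9 elsewhere. The full replicate lists showed little of this excess: they held 277 peaks per Mb inside against 271 on the other chromosomes (replicate 1) and 338 against 307 (replicate 2), with 202 and 229 on the rest of V. Without it, the rest of V had 0.608 times the number by span. Of the 25 highest-ranked regions 8 lie in it. Of the nuclear peaks inside, 22.5% (replicate 1) and 19.9% (replicate 2) were in the top 10% of their list, against 7.53% and 7.87% on the rest of V and 9.84% and 9.86% on the other chromosomes. As the stretch was chosen for its combined peaks, which are mostly high-ranked, this follows in part from the choice and is no separate evidence.

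Whether chance clustering explains the stretch cannot be decided by shuffling bins. The window was found in the same data, and shuffling evens out broad differences along the chromosomes. Shuffled bins gave at most 169 peaks in a window, against 204 (permutation test, p = 0.001, the smallest that 1000 shuffles can give). This shows only that full bins lay together more than under even shuffling. The 5 fullest bins of 100 kb as the whole cause are argued against, but dense stretches spread over more bins stay open. The segment was picked as the fullest window, which favours it in this comparison. Without its 5 fullest bins the segment kept 51.3 peaks per Mb, against 40.6 in the fullest equal window of another chromosome, on III. With peaks within 10 kb counted once the ratio to the rest of the genome fell from 2.25 to 1.52 (permutation test, p = 0.006), and a window on III then held more regions, 93 against 91. Merging takes more from a denser stretch: random placement at the same densities gave 1.63 ± 0.079 (SD of 100 placements, 1.40 to 1.83). The fall therefore does not show that peaks were crowded more inside than elsewhere. The segment itself kept 91 regions, against a mean of 111 under that placement, so its peaks stood closer than that placement gives on average. Extra copies of the segment in this strain may raise peaks of all strengths, and peaks of the lower 50% of ranks were fewer inside in both replicates (33.5% against 53.7% on the rest of V, and 34.8% against 54.2%), which also follows in part from the choice. The replicates placed the right edge 0.2 Mb apart and the left edge 1.8 Mb apart, and without input depth this cannot be told apart from stronger binding. No biological explanation was tested, as the design gives none.

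Of the nuclear peaks among the 1000 highest-ranked of replicate 2, the combined list lacked 8.00% of those inside the segment and 1.14% of those elsewhere (Fisher's exact test, two-sided, adjusted p = 0.00034). In replicate 1 the shares were 7.84% and 3.52%, which did not pass in Fisher's exact test (adjusted p = 0.054). The share inside rests on 8 of 100 peaks in replicate 2 and 8 of 102 in replicate 1. Fisher's exact test treats peaks as independent, which neighbouring peaks are not. The choice of 1000 peaks of replicate 2 rests on peak number alone, and the segment was itself chosen by its combined peaks.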
